A study of Homo sapiens with 4 samples.

How the data were processed

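Transfer RNA was purified by ion exchange from HCT116 cells, an established human colorectal carcinoma line, and from HCT116 cells lacking TRMT1L (TRMT1L KO), a homologue of the tRNA guanosine methyltransferase TRMT1. Each genotype had 2 libraries. They were made by Nano-tRNAseq, in which deacylated tRNA is joined to splint adaptors at both ends, a reverse transcription step opens its fold, and the native RNA strand is read in a nanopore. A modified nucleotide can alter the current and raise the rate at which the base caller reads a wrong base, adds a base or skips one. The error rate is thus an indirect reading of modification: it does not name the modification or give its stoichiometry, and a change of modification can raise it as well as lower it. The labels do not say whether the 2 libraries of a genotype came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

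The deposited values were error rates as a fraction from 0 to 1, per the file headers and the labels: separate sheets of mismatch, insertion and deletion for each library, 12 in all, with 48 tRNA references in rows and 90 nucleotides in columns. The values ran from 0 to 0.873 and no cell was empty. A further sheet gave the canonical position of each nucleotide. Per the submitters' processing notes BWA, SAMtools and bedtools were used. Their versions and settings, the base caller, the read filters, the handling of reads that fit several references and the genome build are not given in the sources used here. The sheets state no read depth, and none was worked out from the fractions. Values were therefore not weighted by depth, no counting interval is given, and references with few reads were not set apart. They hold no reference bases either, so positions are not split by base, and no genome coordinates are given because no build is named. Deletions in a run of like bases can be assigned to any base of the run, and closely similar references can share reads.

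Mismatch, insertion and deletion were added to a summed error for each library and nucleotide. The sum never exceeded 1. The 3721 nucleotides within the tRNAs were the isodecoder sites. The 3621 with a canonical number formed the isoacceptor positions, the others being 100 nucleotides of the variable region. Each of the 48 references was the sole one of its isoacceptor, so the isoacceptor and isodecoder tests share their values, and a median over isodecoders could move nothing and was not run. The 599 nucleotides beyond the tRNA end, in the 3' adaptor, were kept apart. Rates are given as percentages and differences as percentage points, TRMT1L KO minus WT. The arcsine square root of the summed error was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust settings), with Benjamini-Hochberg adjustment over all sites of a test and a threshold of 0.05. Mismatch, deletion and insertion were tested apart in the same way, with no further correction across kinds. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for the rest. Tyrosine had 2 references. Tyr-GTA-2-1 was taken as the main value of tRNA-Tyr at position 27 after the sheets had been seen, and Tyr-ATA-1-1 is given beside it.

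Before the data were examined, 18 lists of positions were fixed: position 26 and position 27 outside tRNA-Tyr, the neighbours of position 27 in tRNA-Tyr, tRNA-Tyr away from it, and canonical positions with known modifications. They were tested with camera at its preset correlation of 0.01, which compares a list with all other positions, and again with an estimated correlation. The list of mitochondrial tRNAs was empty here, leaving 17. The size given for a list is its mean change minus that of all other positions. This measure was chosen after the plain means had been seen, since the plain mean and the test differed in sign for a list. Positions are named by a rule fixed before the data were examined: positions 26 and 27 of tRNA-Tyr, the 10 largest changes past the threshold in each direction with no overlap of the libraries, the leading members of each list, and the 5 largest isodecoder changes in each direction. Any other position given with its values was singled out after the data had been seen. Differences between references of one amino acid were tested with limma on within-library differences, with the robust setting but no trend. Adjustment was over the positions shared by the references. This test was chosen after the data were seen.

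The method was tested on simulated data with the spread of these libraries, over 3621 positions of which 200 were changed. It recovered 23.9% of changes of 5 points, 73.1% of changes of 10 points and 100% of changes of 20 points, with 10 false calls among unchanged positions and 0 calls in a simulation with no change. Only positions where errors made up the majority were lowered and the others raised, so decreases from a lower error were not simulated. The simulated noise was independent between positions and held no library-wide shift. In the real libraries the mean change over all positions was 0.839 points, so these rates may not carry over. Alternatives were no transformation, log2 odds with 0.01 added, no trend or robust setting, positions of at least 5% error, no tRNA ends, each kind of error alone, no insertions, each library left out, the replicate number as a block, libraries centred on their median, and a size rule of 10 points with no overlap.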

Results

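Base-calling errors were compared along 48 nuclear-encoded tRNA references between 2 WT and 2 TRMT1L KO libraries of HCT116 cells. The summed error over the 3721 tRNA nucleotides averaged 31.1% and 31.2% in the WT libraries and 31.9% and 32.1% in the KO libraries. In the 3' adaptor, which carries no tRNA sequence, it averaged 26.5% and 23.02% in WT and 22.7% and 24.9% in KO. Replicates differed at each nucleotide by a median SD of 1.27 points in WT and 1.07 points in KO. Read depth is not stated and was not worked out from the fractions. Messenger RNA and protein of TRMT1L were not measured, so these data hold no direct check of the knockout.

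The first question was whether loss of TRMT1L altered position 27 of tyrosine tRNA, the site of dimethylguanosine that the series assigns to this enzyme. In Tyr-GTA-2-1, the summed error at position 27 fell from 54.7% ± 0.179 in WT to 35.1% ± 4.73 in KO (SD, n = 2 each). This was a change of -19.6 points, with a limma adjusted p of 0.00608. Its parts moved in opposite directions. Deletions fell from 31.98% ± 1.01 to 3.71% ± 0.398 (limma adjusted p = 3.62e-12) and insertions fell from 4.63% to 0.725% (limma adjusted p = 0.00813), while mismatches rose from 18.1% ± 1.48 to 30.6% ± 4.13 (limma adjusted p = 0.0119). In Tyr-ATA-1-1 the summed error at position 27 was 52.7% ± 1.00 in WT and 48.3% ± 1.92 in KO and did not pass the test (limma adjusted p = 0.585), because opposite parts nearly balanced: deletions fell from 30.1% to 10.0% (limma adjusted p = 1.77e-08) and mismatches rose from 16.4% to 34.4% (limma adjusted p = 0.000308). An exact two-sided permutation test of the 4 library values gave p = 0.333 for each of these measures, the smallest it can give with 2 libraries against 2.

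Position 26, where many tRNAs carry a dimethylguanosine made by TRMT1, showed a larger exchange of deletions for mismatches in tyrosine tRNA. In Tyr-GTA-2-1 deletions at position 26 fell from 44.6% ± 1.42 to 9.56% ± 0.499 (limma adjusted p = 2.05e-11) and mismatches rose from 15.9% ± 1.48 to 68.98% ± 3.27 (limma adjusted p = 1.1e-07). The summed error rose from 60.9% ± 0.0958 to 79.04% ± 2.72 (limma adjusted p = 0.00158). In Tyr-ATA-1-1 deletions fell from 32.4% to 5.88% and mismatches rose from 14.3% to 41.1%, each past the limma test, while the summed error was 49.99% in WT and 50.5% in KO (limma adjusted p = 0.977). Tested directly, the rise of mismatches at position 26 was larger in Tyr-GTA-2-1 than in Tyr-ATA-1-1 by 26.3 points (limma adjusted p = 8.66e-15 over 76 positions). So small a p rests largely on variance pooled over those 76 positions, not on the spread of the libraries at position 26. Reads shared between the tyrosine references were not assessed. At position 27 the change of deletions in Tyr-GTA-2-1 differed by -8.16 points (limma adjusted p = 4.84e-06) and that of mismatches, by -5.34 points, did not pass (limma adjusted p = 0.205). The references were not shown to differ in deletions at position 26 (-8.55 points, limma adjusted p = 0.393), nor in the summed error at position 26 (17.6 points, limma adjusted p = 0.0872) or 27 (-15.2 points, limma adjusted p = 0.107).

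**Figure D1:**
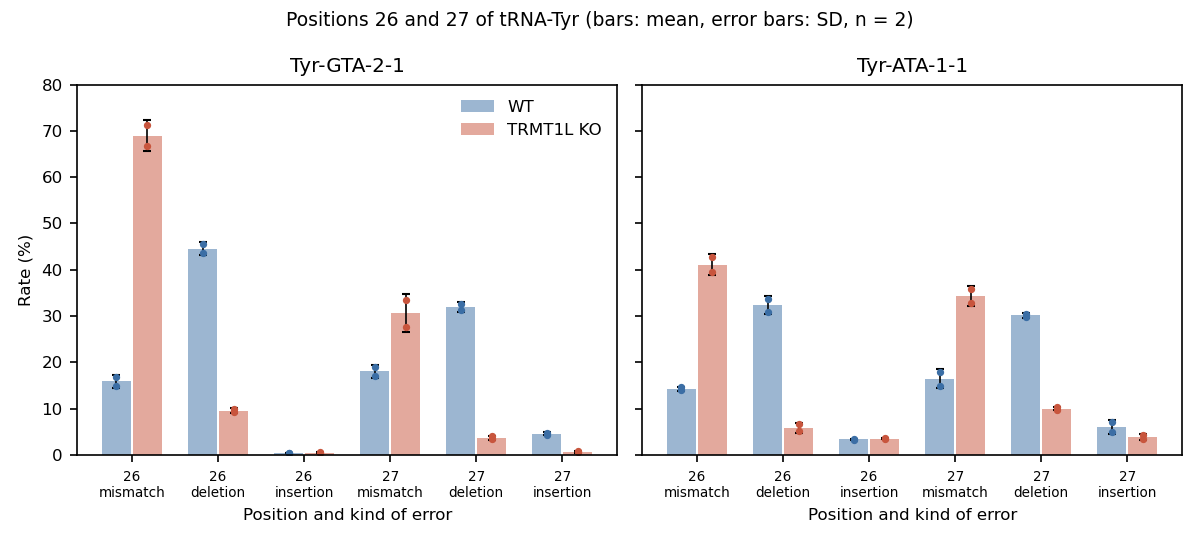
Mismatch, deletion and insertion rates in percent at positions 26 and 27 of both tyrosine references, with WT in blue and TRMT1L KO in red. Bars are means, error bars the SD and points the 2 libraries of each genotype; deletions at position 27 of Tyr-GTA-2-1 go from 31.98% to 3.71% and mismatches at position 26 from 15.9% to 68.98%.

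Across all 3621 isoacceptor positions, 22 passed the limma test, 14 lower and 8 higher in KO, and 339 had an unadjusted p under 0.05. These 22 lay in 7 references, among them 8 in Tyr-GTA-2-1, 4 in Tyr-ATA-1-1, 3 in Cys-GCA-3-1, 3 in Ala-CGC-2-1 and 2 in Ala-TGC-3-1. The isodecoder test over 3721 sites also passed 22. With each library centred on its median, 15 positions passed lower and 3 higher. Leaving out 1 library gave 40 calls without WT replicate 1, 50 without WT replicate 2, 28 without KO replicate 1 and 66 without KO replicate 2.

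**Figure D2:**
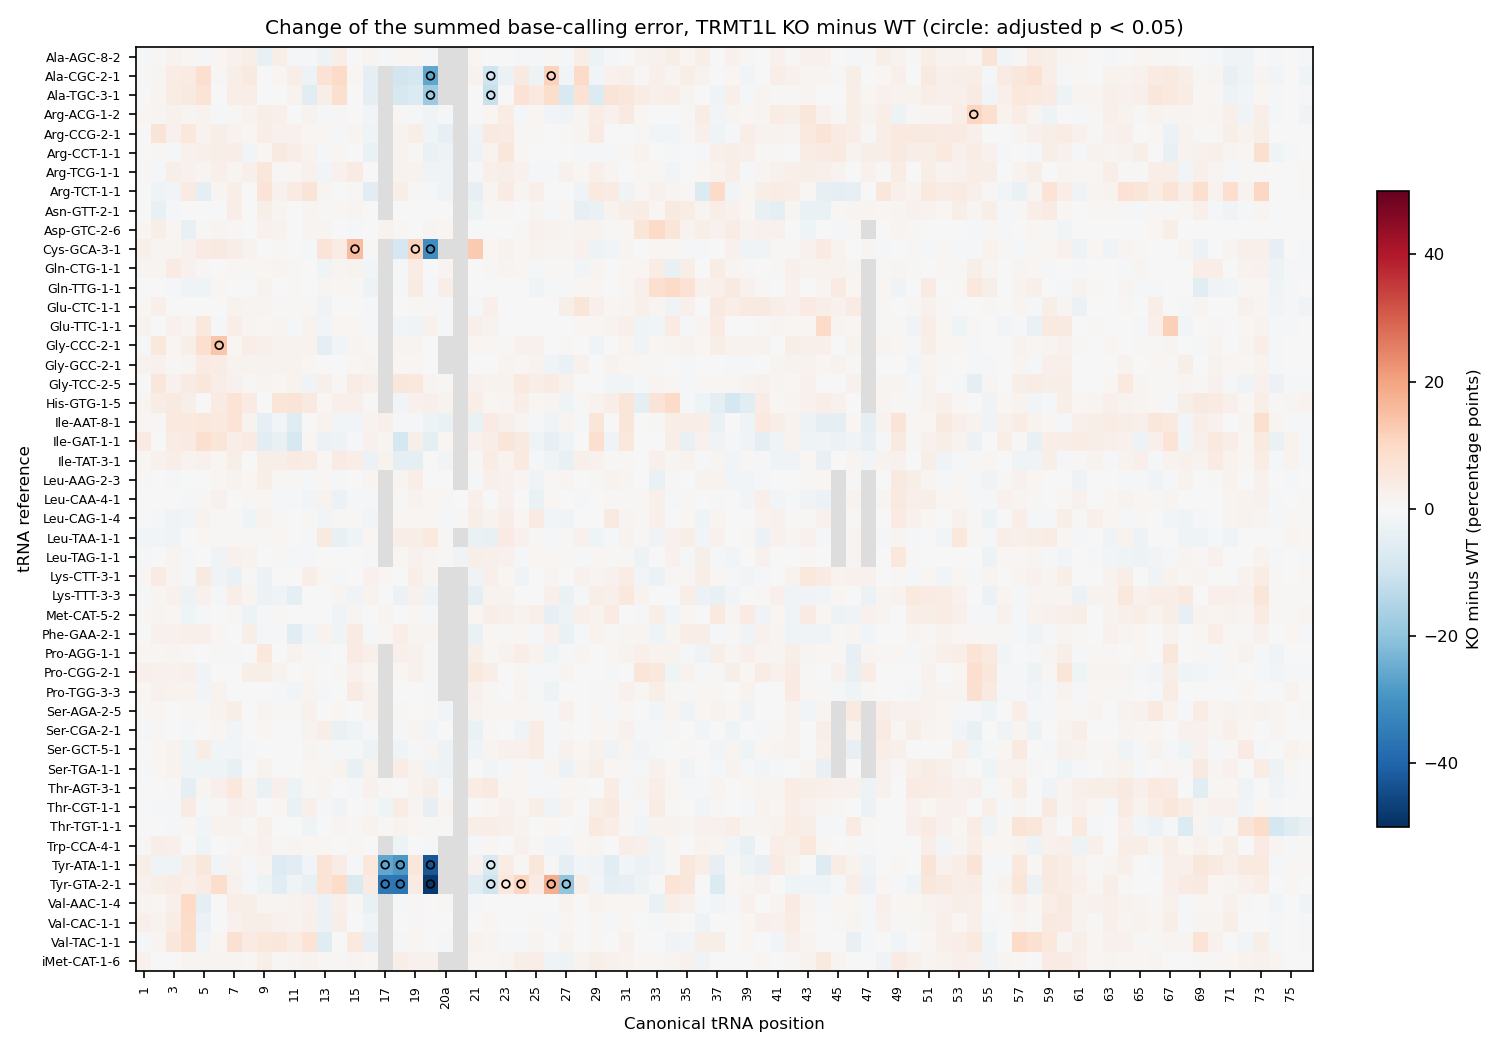
Change of the summed error (KO minus WT, percentage points, colour scale) for each of 48 tRNA references (rows) at each canonical position (columns), with positions a reference lacks in grey. Circles mark the 22 positions past the limma threshold, most of them between positions 15 and 27 of the tyrosine, cysteine and 2 of the alanine references.

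The largest decreases lay in the D arm, the stem and loop on the 5' side of the molecule that commonly carry dihydrouridine. Position 20 fell in 5 references. The summed error went from 81.5% ± 1.33 to 33.2% ± 0.0386 in Tyr-GTA-2-1 (limma adjusted p = 7.4e-07), from 72.9% ± 0.296 to 30.0% ± 3.29 in Tyr-ATA-1-1 (limma adjusted p = 5.24e-06) and from 69.05% ± 1.51 to 38.1% ± 0.757 in Cys-GCA-3-1 (limma adjusted p = 2.24e-05). It went from 49.7% ± 7.75 to 23.6% ± 2.28 in Ala-CGC-2-1 (limma adjusted p = 0.0029) and from 40.7% ± 7.45 to 22.4% ± 0.242 in Ala-TGC-3-1 (limma adjusted p = 0.0175), where the WT libraries were further apart. Mismatches made up most of each decrease, with a change of -45.2 points in Tyr-GTA-2-1 and -20.2 points in Cys-GCA-3-1. In the other 43 references the change at position 20 ranged from -5.00 to 5.03 points with a median of -0.0377, and none passed. Among the alanine references, Ala-AGC-8-2 had 51.01% in WT and 50.2% in KO. The change in Ala-CGC-2-1 differed from it by -25.3 points (limma adjusted p = 1.33e-05 over 75 positions), and that in Ala-TGC-3-1 by -17.5 points (limma adjusted p = 0.00143). These references and this position were picked by the values compared, so the p-values are not separate support.

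**Figure D3:**
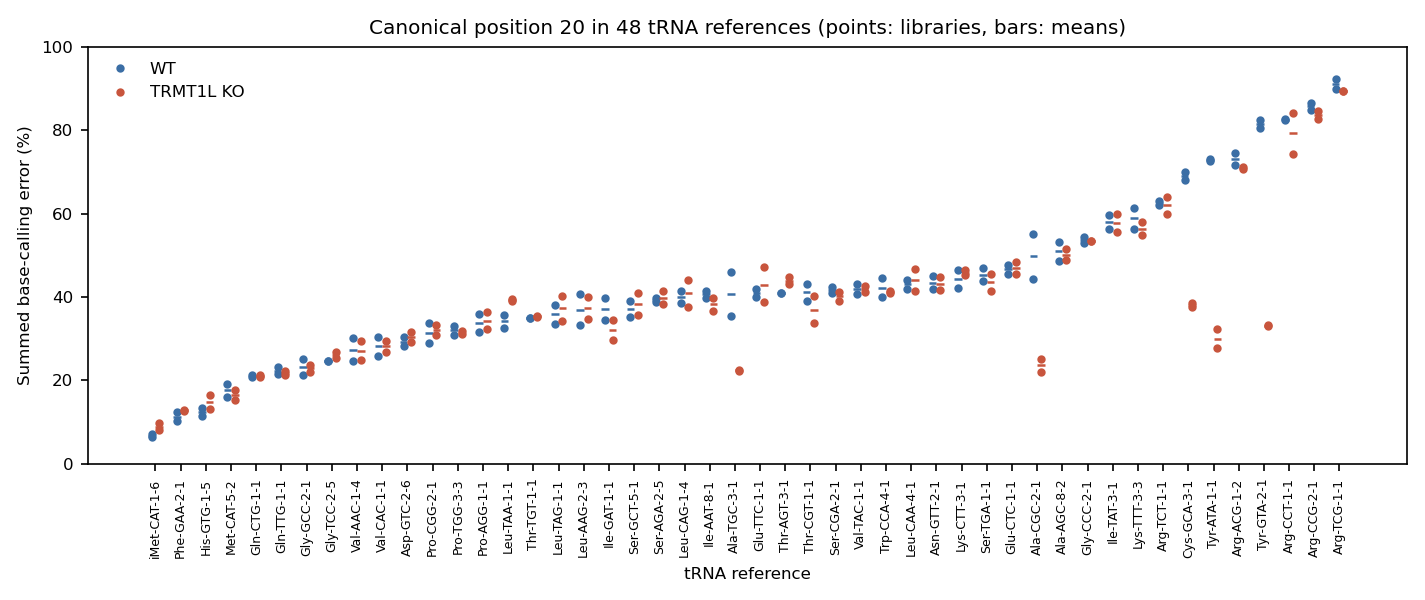
Summed base-calling error in percent at position 20 of 48 tRNA references, ordered by their WT mean, with WT libraries in blue, TRMT1L KO libraries in red and bars for the means. Tyr-GTA-2-1, Tyr-ATA-1-1, Cys-GCA-3-1, Ala-CGC-2-1 and Ala-TGC-3-1 lie lower in KO by 18.3 to 48.3 points, and the other 43 differ by at most 5.03 points.

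In tyrosine tRNA positions 17 and 18 also fell. Tyr-GTA-2-1 fell from 64.6% ± 2.02 to 28.4% ± 2.46 at position 18 and from 58.1% ± 1.82 to 22.3% ± 1.24 at position 17. Tyr-ATA-1-1 fell from 60.3% ± 1.71 to 31.4% ± 2.38 at position 18 and from 44.1% ± 5.81 to 18.1% ± 0.619 at position 17. The largest limma adjusted p of these was 0.000443. Position 19, between them and position 20, had higher values in KO that did not pass, 24.1% in WT and 28.2% in KO in Tyr-GTA-2-1 (limma adjusted p = 0.557) and 30.4% and 36.1% in Tyr-ATA-1-1 (limma adjusted p = 0.469). Within that sum, mismatches in Tyr-ATA-1-1 rose by 10.4 points (limma adjusted p = 0.0102) and deletions fell in both references, with changes of -4.80 and -5.74 points. The remaining decreases, named after their values were seen, were at position 22, with changes of -7.76 to -11.0 points. They were in both tyrosine references, Ala-CGC-2-1 and Ala-TGC-3-1, with limma adjusted p of 0.00997 to 0.0481, the highest in Tyr-ATA-1-1. At position 22 of Tyr-ATA-1-1 and Ala-CGC-2-1 no single kind of error passed (mismatches, limma adjusted p = 0.175 and 0.0561). Without insertions, all decreases that did not pass again were at position 22.

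Beside position 26 of Tyr-GTA-2-1, 7 positions rose. Cys-GCA-3-1 rose from 44.2% ± 0.656 to 59.5% ± 0.265 at position 15 and from 27.9% ± 0.346 to 39.2% ± 1.51 at position 19. Gly-CCC-2-1 rose from 42.4% ± 1.80 to 56.4% ± 2.495 at position 6, Ala-CGC-2-1 from 55.3% ± 1.58 to 66.5% ± 0.906 at position 26, and Arg-ACG-1-2 from 63.1% ± 2.27 to 73.95% ± 0.671 at position 54. Tyr-GTA-2-1 rose from 11.2% to 21.7% at position 24 and from 6.03% to 11.4% at position 23. With each library centred on its median, 5 of the 8 increases no longer passed, those at position 6 of Gly-CCC-2-1, 19 of Cys-GCA-3-1, 26 of Ala-CGC-2-1, 54 of Arg-ACG-1-2 and 23 of Tyr-GTA-2-1. Without insertions the rises at position 24 of Tyr-GTA-2-1 (7.14 points, limma adjusted p = 0.117), 23 of Tyr-GTA-2-1 (5.04 points, 0.0579) and 26 of Ala-CGC-2-1 (11.5 points, 0.0555) did not pass, and at position 24 insertions were the one kind of error that passed by itself (3.42 points, limma adjusted p = 0.00813). The calls at position 19 of Cys-GCA-3-1 (limma adjusted p = 0.143) and 26 of Ala-CGC-2-1 (0.144) were lost without KO replicate 1, and that at 54 of Arg-ACG-1-2 (0.0601) without KO replicate 2.

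Of 17 lists of positions, 4 passed camera with its preset correlation, all lower in KO than the other positions. Positions 20, 20a and 20b, where dihydrouridine and aminocarboxypropyluridine occur, had 5 of 82 members lower and 0 higher, also when adjusted over the list alone. Their mean change relative to that of all other positions was -3.19 points (camera adjusted p = 3.44e-07, and adjusted p = 0.393 with an estimated correlation). The list had a median of -0.267 and a plain mean of -2.28, and none of its 34 members at positions 20a and 20b passed. Positions 16 and 17 had 2 of 62 members lower, both of them position 17 of tyrosine tRNA, and a camera adjusted p of 0.00537, against an adjusted p of 0.393 with an estimated correlation. In this list the median was 0.437 and the mean -0.968. Position 27 outside tRNA-Tyr had 0 of 46 members past the test, with the largest change in Ala-TGC-3-1 (-7.58 points, limma adjusted p = 0.285). Its camera adjusted p was 0.0444, against an adjusted p of 0.393 with an estimated correlation, with a median of 0.182 and a mean of -0.232. Compared with Ala-AGC-8-2, the change at position 27 of Ala-TGC-3-1 differed by -6.98 points (limma adjusted p = 0.0458). The change at position 27 of Ala-CGC-2-1 differed by -0.731 points and did not pass (limma adjusted p = 0.851). Position 26 outside tRNA-Tyr had 1 of 46 members higher, Ala-CGC-2-1, and a camera adjusted p of 0.0469, against an adjusted p of 0.393 with an estimated correlation. Its median was -0.336 and its mean 0.129, against a mean of 0.839 over all positions. Compared with Ala-AGC-8-2, position 26 rose more in Ala-CGC-2-1 by 10.6 points (limma adjusted p = 0.00357) and in Ala-TGC-3-1 by 8.15 points (limma adjusted p = 0.0363). Both were adjusted over 75 positions, and position 26 of Ala-TGC-3-1 did not pass the main test. The alanine references were picked after their values had been seen, so these comparisons are not separate support. None of the 4 lists passed with an estimated correlation. The estimates were 0.0363 for positions 20, 20a and 20b, -0.0120 for 16 and 17, -0.00419 for 27 and -0.0135 for 26. All but the first lay below the preset 0.01, so a larger correlation does not account for those losses. That form of the test rests on the residual spread of only 4 libraries and has little power, so these failures do not decide against the lists.

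The other lists did not pass camera. The neighbours of position 27 in tRNA-Tyr had 2 of 10 members higher, or 4 when adjusted over the list alone (camera adjusted p = 0.0957). Tyrosine tRNA away from position 27 had 6 of 130 members lower, with 2 higher when adjusted over the list alone (camera adjusted p = 0.747). Positions 54 and 55, which commonly hold ribothymidine and pseudouridine, had 1 of 96 members higher, or 3 over the list alone (camera adjusted p = 0.903), and positions 6 and 7 had 1 of 96 higher (camera adjusted p = 0.216). No member passed at position 9 (camera adjusted p = 0.643), position 10 (0.902), position 32 (0.355), position 34 (0.903), position 37 (0.386), position 58 (0.590), positions 38 and 39 (0.0957), positions 46 and 47 (0.195) or positions 48, 49 and 50 (0.195). The largest differences there were 9.62 points at position 34 of His-GTG-1-5, 9.48 points at position 37 of Arg-TCT-1-1 and -8.73 points at position 38 of His-GTG-1-5, none past the test. The others were 7.68 points at position 58 of Val-TAC-1-1, 6.51 points at position 9 of Arg-TCT-1-1, -6.49 points at position 10 of Tyr-ATA-1-1, 6.31 points at position 49 of Ile-AAT-8-1, 6.03 points at position 32 of Pro-CGG-2-1 and -4.94 points at position 47 of Ile-AAT-8-1.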

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

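The crossed block was chosen after the data were seen; the other settings were planned. The 14 decreases were widely kept: 13 or 14 of them passed again without a transformation, with log odds, without trend, with a filter on low error, without the ends, with the block and with centring, and 12 without insertions. Those lost without a transformation, without trend or without insertions were at position 22. Fits with 1 library left out reuse the same libraries and called more positions in all, so passing again there adds little. Centring enlarges decreases, because the KO medians were higher, so a decrease that passes again there adds little too. The increases were less stable. Outside the tests of 1 kind of error, 11 of the 17 named positions that had passed, position 27 of Tyr-GTA-2-1 not counted, did so under all 13 settings. Without KO replicate 1 or KO replicate 2, 20 of the 22 calls were shared with all libraries in use. Of 548 values of single positions and lists under other settings, 462 kept direction and side of the threshold, 54 lost the call, 9 gained it and 23 changed direction, 20 of these with 1 kind of error alone. Of 119 numbers of calls, 75 stayed within 1.5 times the main number, 17 were smaller and 27 larger. Why results moved was not tested, except that kinds of error moving oppositely cancel in a sum. Read depth, which was not worked out, limits every value.

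With mismatch alone, position 27 changed by 12.6 points in Tyr-GTA-2-1 and 17.9 in Tyr-ATA-1-1, 7 lists passed, and position 26 outside tRNA-Tyr lay -0.645 from the other positions and was lost. With deletion alone, isodecoder and isoacceptor calls were 43, with 22 lower and 21 higher. Tyr-ATA-1-1 changed by -20.1 at position 27 and -26.5 at 26, Tyr-GTA-2-1 by -35.0 at 26, Cys-GCA-3-1 by -6.45 at 19 and Ala-TGC-3-1 by 2.09 at 27. Then 2 lists passed, and the lists of position 26 (-0.0881), position 27 (-0.0862) and positions 16 and 17 (-0.401) were lost. With insertion alone, isodecoder calls were 4 (2 lower, 2 higher) and isoacceptor calls 3 (1 lower, 2 higher). Direction changed, with no call, at position 20 of Tyr-GTA-2-1 (2.30), Tyr-ATA-1-1 (1.64) and Cys-GCA-3-1 (0.549), position 18 of Tyr-GTA-2-1 (0.957), 15 of Cys-GCA-3-1 (-0.961), 26 of Ala-CGC-2-1 (-0.287), 54 of Arg-ACG-1-2 (-0.478), 27 of Ala-TGC-3-1 (0.0524), 34 of His-GTG-1-5 (-0.462) and 47 of Ile-AAT-8-1 (0.814). It changed too for all 4 lists, 26 (0.0137), 27 (0.0844), 20 to 20b (0.111) and 16 and 17 (0.0440), none of which passed (adjusted p = 0.877 to 0.886), while 2 of the other lists passed. Without insertions 5 isoacceptor positions were higher.

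Without a transformation the list of position 26 was lost (-0.720, adjusted p = 0.0610). Without the tRNA ends 2 lists passed, those of 26 (-0.708) and 27 (-1.07) being lost. Centring left 3 isodecoder and 3 isoacceptor increases, turned position 26 of Tyr-ATA-1-1 to -0.743 and left 2 lists, 26 (-0.720) and 27 (-1.08) being lost. With an estimated correlation 0 lists passed: 26 (-0.720), 27 (-1.08), 20 to 20b (-3.19) and 16 and 17 (-1.84). The plain mean of a list, in place of its mean against other positions, changed sign in 4 of 16 settings for 26, 4 for 27, 1 for 20 to 20b and 1 for 16 and 17.

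Leaving out 1 library, with a lone library assumed to vary like the other genotype, gave 29 to 77 isodecoder calls (17 to 23 lower, 12 to 54 higher) and 28 to 66 isoacceptor calls (11 to 45 higher). It gave 2 to 8 lists, -0.965 to -0.474 for list 26, -1.46 to -0.706 for list 27, and -2.03 to 3.07 points at position 26 of Tyr-ATA-1-1. The call of list 26 was lost each time (adjusted p = 0.132 without WT replicate 1, 0.106 without WT replicate 2, 0.0699 without KO replicate 1, 0.308 without KO replicate 2), and that of list 27 without WT replicate 2 (0.335) and without KO replicate 2 (0.308). Position 27 of Tyr-GTA-2-1 kept its call, at -22.9 to -16.3 points.

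Same-numbered libraries did not deviate together (correlation -0.251), so the numbers give no pairing. With 2 libraries per genotype the crossed pair WT1 and KO2 must give the opposite value, 0.251. Structure shared across the numbers is therefore not excluded. With the replicate block, 5 isodecoder and 4 isoacceptor positions were higher and the list of position 26 was lost (-0.720); 13 of the 14 decreases were shared. The crossed replicate block gave 69 isodecoder calls (25 lower, 44 higher) and 74 isoacceptor calls (25 lower, 49 higher). A median over isodecoders and the split by reference base were not run.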

Other observations

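Tests of 1 kind of error showed changes that the summed error did not. All 22 decreases in deletions lay in the 5 references in which position 20 fell. Of the 21 increases in deletions, 13 lay elsewhere, each under 11 points. Examples, named after their values were seen, were deletions that rose from 1.56% ± 0.882 to 4.91% ± 0.469 at position 1 of Ile-GAT-1-1 (SD, n = 2 each; limma adjusted p = 0.00104), from 9.19% ± 0.469 to 15.8% ± 1.50 at its position 12 and from 2.80% ± 0.599 to 6.00% ± 0.366 at position 6 of Ile-AAT-8-1. At position 1 of Ile-GAT-1-1 the WT libraries had 2.18% and 0.935%. The fit took no account of the number of reads behind such low rates, so its p-values leave out counting noise. In Cys-GCA-3-1 mismatches rose at position 21 from 29.1% ± 3.69 to 46.6% ± 5.19 (limma adjusted p = 0.00822) and at position 19 from 14.5% ± 0.789 to 32.3% ± 0.951 (limma adjusted p = 0.000103) beside the fall at position 20. At position 19 deletions fell in all 5 references, with changes of -4.80 to -6.55 points. In the 3' adaptor 0 of 599 nucleotides passed the limma test and 7 had an unadjusted p under 0.05.

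All tests in the next 2 paragraphs were put to these questions after the results they bear on had been seen. The fall at position 20 came in 5 of 48 references. Its median change over all 48 references was -0.246 points. The 5 were picked by their fall, so this median could not test a library-wide shift of the error rate. The mean summed error over all tRNA nucleotides was higher in KO, by 0.828 points. The higher mean in KO argues against a library-wide fall of the error rate. All 14 decreases passed again with each library centred on its median. Centring on the higher KO medians makes each decrease larger, so this adds no support. It moved the plain mean of positions 20, 20a and 20b from -2.28 to -3.54 points. Whether an alteration of 1 nucleotide was read as changes over its neighbours was not tested, nor were reads shared between like references. Loss of TRMT1L, the difference the design names, and any other difference between the KO and WT lines stay open, as the sheets name no modification.

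At positions 26 and 27 of tyrosine tRNA deletions gave way to mismatches. A fall of deletions at position 26 in all tRNAs is argued against by the median deletion change there of 0.411 points in the other 46 references, with a range of -3.16 to 5.15. Mismatches at position 26 of these references changed by a median of -0.0837 points, with a range of -5.34 to 7.79. Deletions fell at both positions, by -35.0 and -28.3 points at 26 and 27 of Tyr-GTA-2-1 and by -26.5 and -20.1 points in Tyr-ATA-1-1. This argues against a mere move of deletions from 1 of the 2 positions to the other. Which of the 2 positions gave rise to the deletions was not tested, since the sheets hold no reference bases. Loss of TRMT1L and any other difference between the lines are confounded here and stay open.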
